A study of Mus musculus with 6 samples.

How the data were processed

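Midbrain RNA from the Lhx5-TRAP line DT154 was measured after affinity purification by RNA sequencing in 6 libraries, 3 IP and 3 input. Groups and replicate numbers were taken from the sample titles. A separate label calls the input libraries unbound, and the labels do not settle which is right. Per the labels' protocols, tagged polysomes were immunopurified with anti-EGFP antibodies on magnetic beads and RNA was purified from them.

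The deposited values are raw read counts per gene symbol, 1 file per library, with no normalization. Reads were aligned with STAR 2.0.0e and counted with HTSeq on genome build mm10, per the submitters' processing notes. The gene annotation, the strand setting and the counting mode are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart, and genes with near-identical copies are uncertain because reads with several alignments were left out of gene counts. Each file has 32531 gene entries, an entry for unknown genes and 5 summary lines that were kept out of library totals and tests. Alignments that were not unique made up 44.2% ± 0.402 of all lines' counts in IP and 32.5% ± 0.595 in input (SD, n = 3 each). Ambiguous reads made up 1.64% ± 0.0451 and 9.35% ± 1.48, and reads outside any feature 7.79% ± 0.0611 and 13.7% ± 1.07.

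Symbols were matched to GENCODE M21 (GRCm38), with 23155 entries matched by symbol and 773 through an older symbol, for positions and gene classes. Genes with low counts were removed with filterByExpr by group (minimum count 10, minimum total 15), which kept 17197 and removed 15334. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust dispersion, quasi-likelihood F test, two-sided, group as the only term). Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Changes over 2-fold were tested with glmTreat in the same fit. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library totals. At the depth of 38058239 to 45841499 counts, 3 counts correspond to 0.0654 to 0.0788 CPM, and such floors cover counting error only.

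Gene lists were compared with all other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. The 31 lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover neuron classes, pan-neuronal genes, neuropeptides, channels, receptors, glia, vessels, blood, neighbouring regions, immediate early genes, oxidative phosphorylation, ribosomal proteins, nuclear noncoding RNAs and histones. The list of mitochondrially encoded genes had 0 tested members and is not analysed here. Named genes were Lhx5 and Rpl10a, the 12 largest rises and falls among called genes with an average log2 CPM of at least 3 and 1 direction in all 3 pairs, and of each list the up to 3 most abundant members that passed in its commoner direction and 1 that passed in the other. Symbols made of Gm and digits, Rik or LOC were left out of the largest changes. Stmn3, Adcyap1, Pnoc, Kcnk3, Hcn3, Gad1, Gad2, Slc6a3, Tph2, Pcp2, Car8, Drd1, Ttr and the genes near Lhx5 were named after their values were seen.

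Same-numbered IP and input libraries carry the same lane number in their labels, so the number marks a shared sequencing lane. As a check, deviations from the group means correlated at 0.155, 0.074 and 0.051 within the same-numbered pairs, and each library correlated best with the one of its own number. Replicates within a group correlated at 0.971 to 0.985 (Pearson, log CPM, across genes). Chi-square statistics per degree of freedom within groups were 27.1 to 84.6, so no library was a copy of another.

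In simulated counts for the 17197 genes of IP against input, 200 genes were changed, as many up as down. Of genes changed 2-fold 60% were recovered, and of those changed 4-fold 94%, and 5.5% of calls were false. The real comparison called 9261 genes, with more past 2-fold downward than upward, so these rates need not hold for it. Alternatives were RLE, upper-quartile and library-total scaling, TMM without abundant genes, other low-count filters, thinning to the smallest library, a replicate block, DESeq2 1.42.0, limma-voom, a threshold of 0.01 and leaving out libraries or pairs. The alternatives added after seeing the data were protein-coding genes only, leaving out 4 abundant RNAs, and leaving out IP replicate 2 with input replicate 3. Fits without a library filtered genes afresh, so the number of tested members of a list can differ.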

Results

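Translating ribosome affinity purification (TRAP) was used to profile RNA from the midbrain of adult Lhx5-TRAP mice of line DT154. In this transgenic line a fusion of EGFP with the ribosomal protein Rpl10a is driven by regulatory sequences of Lhx5, a LIM homeodomain transcription factor, and antibodies against EGFP pull down polysomes from cells that carry the tag. The mice were untreated controls. The series held 3 libraries of immunopurified RNA (IP) and 3 libraries titled as input, and a second label calls the latter unbound, so they may be the whole homogenate or what was left after the pull-down. They are called input here. Gene totals ran from 38058239 to 45841499 counts per library. A mean of 18846 ± 58 genes had a count in IP and 21071 ± 14.7 in input (SD, n = 3 each). The labels do not say that replicates were separate animals, so the p-values measure the spread between these samples, which may be technical. The question was which RNAs are on the ribosomes of tagged neurons relative to the surrounding midbrain.

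Lhx5 itself was 15.3-fold higher in IP, at 50.7 ± 4.81 CPM (counts scaled to library size) against 3.31 ± 0.963 in input (SD, n = 3 each). The log2 fold change of Lhx5 was 3.93 (SE 0.23), with an adjusted p of 1.29e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. IP replicates 1, 2 and 3 had 46.8, 56.0 and 49.1 CPM of Lhx5, and the input replicates had 3.92, 3.81 and 2.20. Lhx5 is a protein-coding gene on chromosome 5 from 120431699 to 120441223 (GENCODE M21, GRCm38, the assembly also called mm10). Transcripts of the transgene could add to its count. Rpl10a, the gene of the tagged protein, gave 7.03 ± 0.0220 CPM in IP and 7.80 ± 1.53 in input, with a log2 fold change of -0.15 (SE 0.20, adjusted p 0.548). Of 13 genes tested within 300 kb of Lhx5, itself included, 6 were higher and 2 lower in IP. Plbd2, a lysosomal protein gene, was higher by 1.30 (SE 0.27), and Rasal1, a Ras GTPase activator gene, had a log2 fold change of -1.84 (SE 0.31).

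Several of the largest rises in IP were of transcription factor genes, read from single genes and not from a list test. Foxb1, a forkhead factor of the mammillary and thalamic lineage, rose by a log2 fold change of 4.01 (SE 0.34). The homeodomain factor Uncx rose by 3.44 (SE 0.27). Lhx1, the closest relative of Lhx5, rose by 3.20 (SE 0.32), and reads of its antisense neighbour cannot be told apart without strand. The bHLH-PAS factors Sim1 and Npas1 rose by 3.20 (SE 0.46) and 3.15 (SE 0.40), and Nkx2-1, a ventral forebrain and hypothalamic factor, by 3.16 (SE 0.59). Without input replicate 3, Sim1 stood at 3.91 and Nkx2-1 at 4.15. Other genes among the largest rises were C1ql2, a secreted C1q-like synaptic protein (3.42, SE 0.49), Rprm, a cell cycle regulator (3.31, SE 0.24), Sncg, the gene of gamma-synuclein (3.02, SE 0.41), and Nccrp1 (3.50, SE 0.63). Nccrp1 stood at 4.58 without input replicate 1. A rise in all 3 same-numbered pairs and an adjusted p under 0.05 were conditions for naming these genes. Lhx5, named beforehand, also rose in all 3 pairs. Their adjusted p, Lhx5 included, was 0.00253 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

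Among 17197 genes tested, 4467 were higher and 4794 lower in IP, and 7936 passed in neither direction. A change shown to exceed 2-fold was found for 387 genes upward and 2214 downward. Of the calls, 48.2% were upward, against 38.1% with upper-quartile scaling. The median log2 fold change of all tested genes was -0.01, and it was -0.17 with upper-quartile scaling and -0.15 with library totals alone. Protein-coding genes made up 14674 of those tested, with 4260 higher and 3713 lower. Of 1630 entries whose name matched no gene of the annotation, 97 were higher and 819 lower. Leaving out IP replicate 2, high in Purkinje cell genes, and input replicate 3, high in striatal genes, gave 3490 genes higher and 4289 lower. Past 2-fold were 291 and 1872. The libraries kept were not free of markers of other regions, described further on, with 338 CPM of the choroid plexus gene Ttr in input replicate 1.

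**Figure D1:**
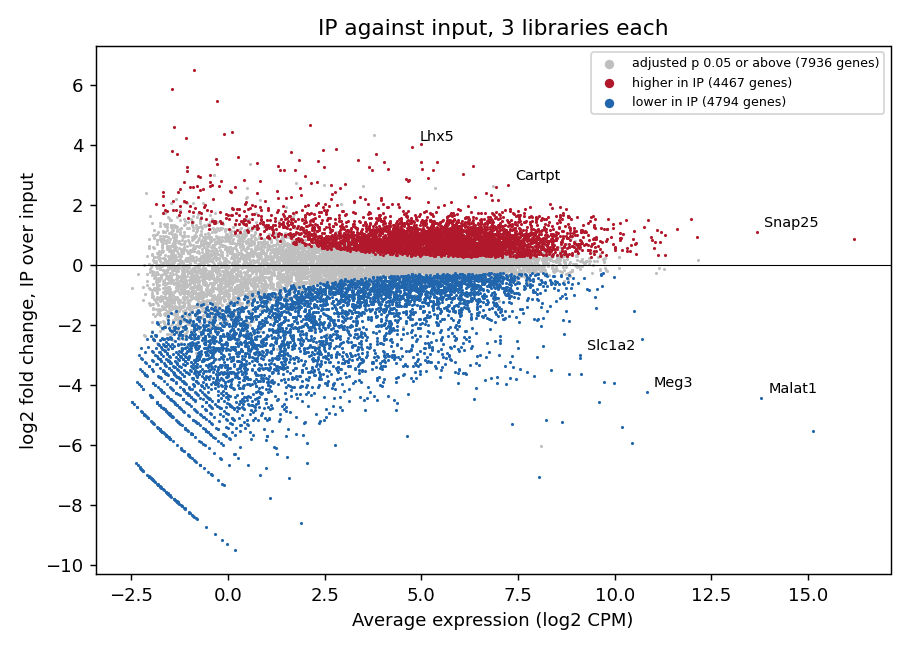
Log2 fold change of IP over input (vertical axis) against average expression in log2 CPM (horizontal axis) for the 17197 tested genes, 1 point per gene, from 3 libraries per group. The 4467 genes higher in IP are red, the 4794 lower are blue and the 7936 others are grey. Lhx5 lies at 3.93 and Malat1 at -4.44.

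Long noncoding RNAs kept in the nucleus fell. Malat1 fell by 4.44 on the log2 scale (SE 0.34) and took 2.84% ± 0.475 of the gene counts in input against 0.117% ± 0.0503 in IP (SD, n = 3 each). Meg3, an imprinted noncoding RNA, fell by 4.25 (SE 0.21), and Snhg11 fell by 3.91 (SE 0.19). Of 16 tested noncoding RNAs of this list 12 fell, 2 rose and 2 did not pass, with the same counts adjusted over the list alone and 1 risen without IP replicate 1, IP replicate 2, input replicate 1 or input replicate 3 and with every other scaling (camera adjusted p = 1.64e-10, and adjusted p = 0.215 with an estimated correlation). Peg13, an imprinted RNA, rose by 1.36 (SE 0.11). The 12 largest falls by the rule were all entries named by sequence records with no gene name, at log2 fold changes from -7.08 to -4.56. Among entries with gene names, chosen after their values were seen, Sox1, an HMG-box factor of neural progenitors, fell by 4.51 (SE 0.36). Igf2, made by meningeal and vascular cells, fell by 4.11 (SE 0.17), and Fam107a, an astrocyte-rich gene, fell by 3.97 (SE 0.19).

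Glial, vascular and blood genes were lower in IP. All 20 oligodendrocyte genes fell, among them the myelin genes Mbp (log2 fold change -3.12, SE 0.13) and Mobp (-3.50, SE 0.32). The list median was -3.37 (camera adjusted p = 3.3e-39, and adjusted p = 0.116 with an estimated correlation). Of 20 astrocyte genes 17 fell and 3 did not pass, with the glutamate transporter gene Slc1a2 at -3.02 (SE 0.21) and a list median of -3.01 (adjusted p = 1.22e-16, and adjusted p = 0.365 with an estimated correlation). Of 20 microglial genes 19 fell and 1 did not pass, with the purinergic receptor gene P2ry12 at -3.87 (SE 0.36) and the growth factor receptor gene Csf1r at -3.44 (SE 0.38). Their median was -3.61 (adjusted p = 1.11e-10, and adjusted p = 0.365 with an estimated correlation). Of 13 oligodendrocyte precursor genes 10 fell, 1 rose (0 without IP replicate 1, IP replicate 2, input replicate 2 or input replicate 3 and with upper-quartile scaling) and 2 did not pass, with Olig1 at -3.32 (SE 0.16) and a median of -3.27 (adjusted p = 6.69e-08, and adjusted p = 0.115 with an estimated correlation). Adjusted over the list alone, the counts of these 4 lists were the same.

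Of 18 endothelial genes 12 fell and 6 did not pass, and 13 fell adjusted over the list alone. Without input replicate 2, 8 fell and 1 rose, and without input replicate 1, 9 fell. Without IP replicate 3 or input replicate 3, 14 of 19 tested fell. The organic anion transporter gene Slco1a4 stood at -3.82 (SE 0.31), and the median was -2.43 (camera adjusted p = 0.00589, and adjusted p = 0.573 with an estimated correlation). Of 18 mural and fibroblast genes 16 fell and 2 did not pass, with the pericyte gene Rgs5 at -3.58 (SE 0.33) and a median of -2.75 (adjusted p = 2.51e-06, and adjusted p = 0.392 with an estimated correlation). The 4 blood genes tested fell, with the globin gene Hbb-bs at -3.85 (SE 0.41), although near-identical globin genes share reads (adjusted p = 0.00759, and adjusted p = 0.392 with an estimated correlation). Of 13 ependymal and choroid plexus genes 7 fell and 6 did not pass, with a median of -3.14 (adjusted p = 0.0293, and adjusted p = 0.801 with an estimated correlation). Without input replicate 3 that median was -2.29 and the list was no longer called (adjusted p 0.0737). Adjusted over the list alone, the mural, blood and choroid counts were the same. Ttr, the transthyretin gene of the choroid plexus, had 1266 CPM in input replicate 3, 338 in input replicate 1 and 7.24 in input replicate 2.

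**Figure D2:**
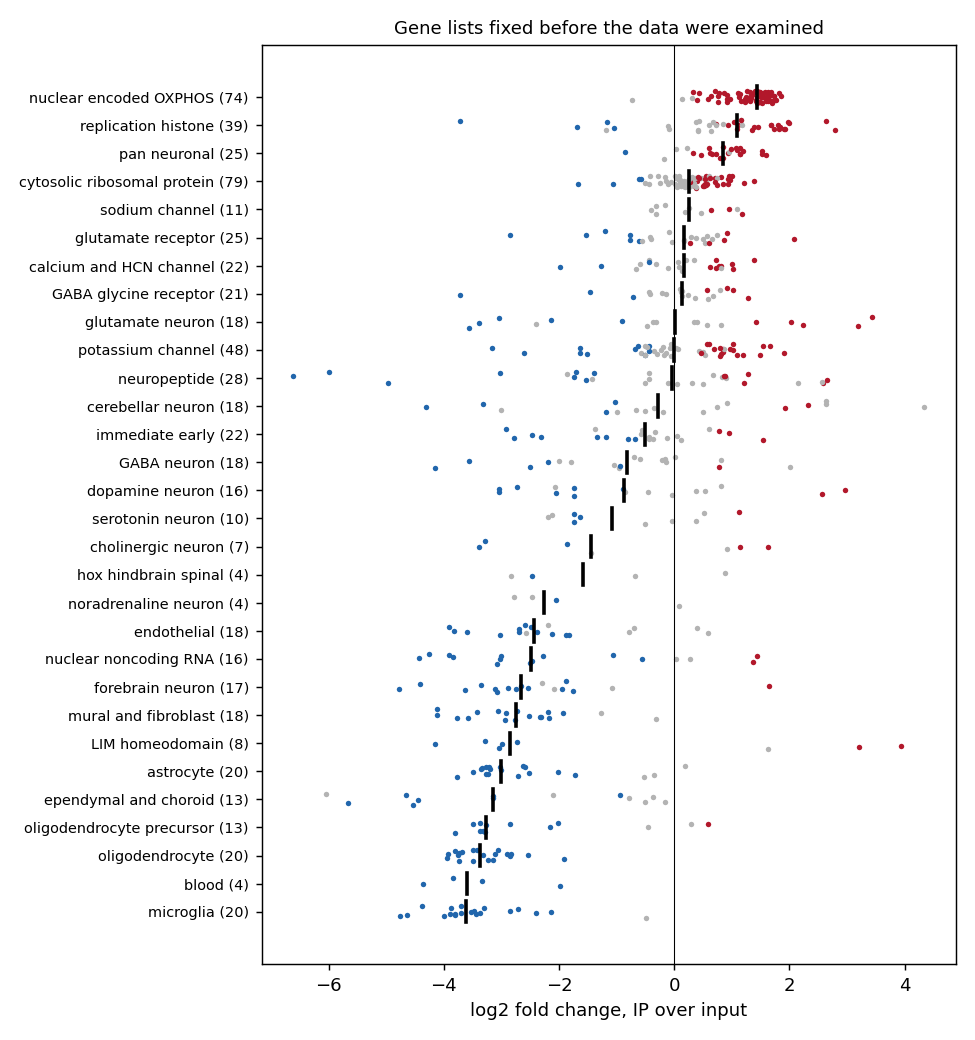
Log2 fold change of IP over input (horizontal axis) for each tested member of the 30 gene lists, 1 point per gene, with a black bar at each list's median and the number of members in brackets. Red points rose, blue points fell and grey points did not pass. Medians run from -3.61 for microglia to 1.43 for oxidative phosphorylation.

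Genes that all neurons use rose. Of 25 pan-neuronal genes 20 rose, 1 fell and 4 did not pass, and 21 rose adjusted over the list alone. Snap25, a SNARE protein of the presynaptic membrane, rose by 1.10 (SE 0.17), Vsnl1, a neuronal calcium sensor, by 1.52 (SE 0.15), and Stmn3, a stathmin, by 1.60. Map2, a dendritic microtubule protein, fell by 0.85 (SE 0.11). The list median was 0.86 (camera adjusted p = 8.53e-06, and adjusted p = 0.365 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose further, with 71 of 74 higher, 0 lower and 3 not passed, and 72 higher adjusted over the list alone. Their median was 1.43 (adjusted p = 7.23e-36, and adjusted p = 0.365 with an estimated correlation), and Cox4i1, a cytochrome c oxidase subunit, rose by 1.23 (SE 0.15). Of 79 cytosolic ribosomal protein genes 27 rose, 4 fell and 48 did not pass, against 23 and 3 adjusted over the list alone and 17 risen without input replicate 1. Their median was 0.27 and was 0.11 with upper-quartile scaling, where 18 rose and 7 fell (adjusted p = 0.01, and adjusted p = 0.801 with an estimated correlation). Rpl41 rose by 1.01 (SE 0.15) and Rps4x fell by 0.61 (SE 0.11), and reads shared with pseudogenes leave these genes uncertain. Of 39 replication-dependent histone genes 21 rose, 4 fell and 14 did not pass, with the same counts adjusted over the list alone and 13 risen without IP replicate 2 or without input replicate 1, and 2 fallen without input replicate 3. Their median was 1.08 (adjusted p = 0.00552, and adjusted p = 0.618 with an estimated correlation), and Hist1h4d rose by 1.11 (SE 0.14) while Hist1h2bc fell by 3.71 (SE 0.29). Histone genes have near-identical copies, so single values are uncertain.

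Transmitter genes split in direction. Slc17a6, the vesicular glutamate transporter 2 gene, rose by 1.42 (SE 0.29), from 207 ± 69.4 CPM in input to 554 ± 153 in IP (SD, n = 3 each). Of 18 glutamatergic genes 5 rose, 5 fell and 8 did not pass, with Nhlh2, a bHLH factor, up by 2.23 (SE 0.15) and Tcf7l2, a thalamic and habenular Wnt effector, down at -3.56 (SE 0.24). The vesicular GABA transporter gene Slc32a1 rose by 0.78 (SE 0.20). Gad1 and Gad2, the GABA synthesis genes, had log2 fold changes of -0.13 (SE 0.14) and -0.16 (SE 0.20) and did not pass. Of 18 GABAergic genes 1 rose, 5 fell and 12 did not pass. The count of falls was 3 without IP replicate 2, IP replicate 3, input replicate 1 or input replicate 2, and 8 of 19 tested, with 2 risen, without input replicate 3. The camera test called neither list, with adjusted p of 0.5 and 0.539, and the counts adjusted over the list alone were the same.

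Single genes of dopamine neurons fell in IP, while no monoamine list was called. Th, tyrosine hydroxylase of catecholamine synthesis, stood at -2.05 (SE 0.32), Aldh1a1, an aldehyde dehydrogenase of a dopamine neuron subset, at -3.04 (SE 0.30), and Ddc, the aromatic amino acid decarboxylase gene, at -1.73 (SE 0.27). Foxa2, a floor plate factor, rose by 2.97 (SE 0.42). Of 16 dopaminergic genes 2 rose, 7 fell and 7 did not pass (camera adjusted p 0.51), and of 10 serotonergic genes 1 rose, 3 fell and 6 did not pass (camera adjusted p 0.636). Adjusted over the list alone, 0 serotonergic genes rose and the other counts were the same, and 0 rose without IP replicate 1, IP replicate 2, IP replicate 3, input replicate 2 or input replicate 3 and with upper-quartile scaling. Input replicate 3 held little of these RNAs, with 4.99 CPM of the dopamine transporter gene Slc6a3 against 62.4 and 52.3 in input replicates 1 and 2, and 0.30 CPM of the serotonin synthesis gene Tph2 against 12.6 and 10. Without input replicate 3, 9 of 18 dopaminergic and 5 of 10 serotonergic genes fell, and both lists were called lower (adjusted p 0.00429 and 0.0262, and adjusted p = 0.583 for both with an estimated correlation). Of 4 noradrenergic genes 1 fell and 3 did not pass (adjusted p 0.559), and 2 fell without IP replicate 1 and 3 without input replicate 3. Of 7 cholinergic genes 2 rose, 3 fell and 2 did not pass (adjusted p 0.888), and 1 fell without IP replicate 2, IP replicate 3 or input replicate 3, 4 fell without input replicate 2, and 1 rose without IP replicate 1, IP replicate 2 or input replicate 2. The counts of these last lists were the same adjusted over the list alone.

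Markers of neighbouring regions set single libraries apart. Pcp2, a Purkinje cell gene of the cerebellum, had 77.9 CPM in IP replicate 2 and 0.17 and 0.12 in IP replicates 1 and 3. Car8, also rich in Purkinje cells, had 555 CPM in IP replicate 2 against 22.4 and 20.9. In input replicates 1, 2 and 3, Pcp2 had 0.5, 3.03 and 0.3 CPM and Car8 had 23.9, 53.1 and 19.1. Of 18 cerebellar genes 2 rose, 4 fell and 12 did not pass (camera adjusted p 0.961). Cbln1, a synaptic organiser, rose by 2.33 (SE 0.16), and Etv1, an ETS factor, fell by 3.31 (SE 0.17). The list median was -0.28, and it was -0.99 without IP replicate 2 and 0.33 without input replicate 2. Input replicate 3 was high in striatal RNA, with 73.3 CPM of the dopamine receptor gene Drd1 against 11.2 and 3.37 in input replicates 1 and 2, and 316 CPM of Ppp1r1b, a striatal phosphatase regulator, against 55.1 and 21.7. Of 17 forebrain genes 13 fell, 1 rose and 3 did not pass, with Nrgn, neurogranin, at -1.75 (SE 0.15) and Mef2c at -2.53 (SE 0.34). Of these genes, 9 fell without IP replicate 1 or IP replicate 3, 10 without input replicate 3 and 11 without IP replicate 2 or input replicate 1. Their median was -2.66 (adjusted p = 0.000505, and adjusted p = 0.392 with an estimated correlation) and was -2.15 without input replicate 3. Emx2, a cortical homeodomain factor, rose by 1.64 (SE 0.18). Of 4 Hox and hindbrain genes 1 fell and 3 did not pass (adjusted p 0.861), and 2 of 7 tested fell without IP replicate 1, 0 of 8 without IP replicate 2, where 1 rose, and 4 of 8 without input replicate 3. Counts adjusted over the list alone were the same for these 3 lists.

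**Figure D3:**
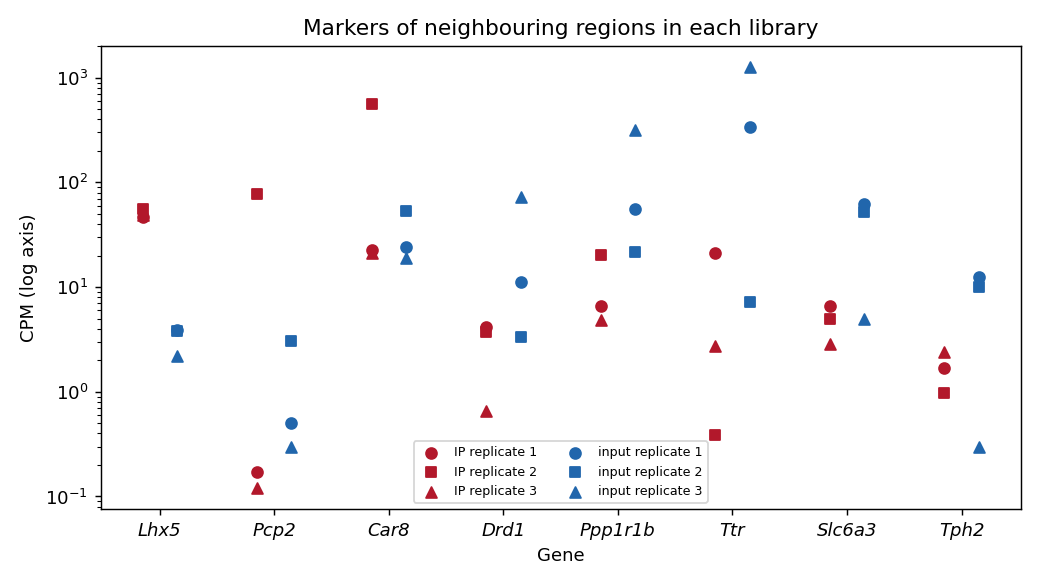
CPM on a log axis (vertical) of 8 genes (horizontal axis) in each library, 1 point per library, with IP in red, input in blue and the replicate number as the symbol. Pcp2 reaches 77.9 CPM in IP replicate 2 alone, and Slc6a3 is at 4.99 CPM in input replicate 3 against 62.4 and 52.3 in the other input libraries.

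LIM homeodomain genes divided. Lhx5 and Lhx1 rose, 5 of the 8 tested fell and 1 did not pass, with the same counts adjusted over the list alone. Lhx9 fell by 3.05 (SE 0.34) and Lhx2 by 2.98 (SE 0.46), and Lhx2 stood at -3.59 without IP replicate 2. The list median was -2.86, its mean was -0.93 and the camera test pointed upward without a call (adjusted p 0.961). Of 28 neuropeptide genes 6 rose, 8 fell and 14 did not pass (adjusted p 0.696). Cartpt, the CART peptide gene, rose by 2.65 (SE 0.33), Adcyap1, the PACAP gene, by 2.58 (SE 0.34) and Pnoc, the prepronociceptin gene, by 1.28 (SE 0.21). The hypothalamic gene Hcrt, orexin, fell by 4.97 (SE 0.65), and stood at -6.03 without IP replicate 2. Neuropeptide counts were the same adjusted over the list alone.

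Channel and receptor genes moved in both directions, and none of their lists was called by camera. Of 48 potassium channel genes 18 rose, 10 fell and 20 did not pass (19 rose adjusted over the list alone, adjusted p 0.377), and 6 fell without input replicate 1. Kcnk3, a two-pore leak channel, rose by 1.49 and Kcnip3, a channel-interacting calcium sensor, fell by 1.51 (SE 0.17). Of 22 calcium and HCN channel genes 8 rose, 3 fell and 11 did not pass, also over the list alone (adjusted p 0.377), against 7 and 6 with upper-quartile scaling, with Hcn3, a pacemaker channel, up by 1.39. Of 11 sodium channel genes 3 rose and 8 did not pass (2 rose adjusted over the list alone, adjusted p 0.391), with Scn2b, a channel beta subunit, up by 0.64 (SE 0.09), and 6 of 12 tested rose without IP replicate 3 and 1 fell without IP replicate 1, while 2 rose and 2 fell with upper-quartile scaling. Of 21 GABA and glycine receptor genes 4 rose, 3 fell and 14 did not pass, against 3 and 2 adjusted over the list alone (adjusted p 0.539). The count that rose was 1 without IP replicate 1, 2 without IP replicate 2 or input replicate 3 and 9 of 22 tested without IP replicate 3. Of 25 glutamate receptor genes 5 rose, 6 fell and 14 did not pass, also over the list alone (adjusted p 0.887), with Grm4, a metabotropic receptor, up by 0.87 (SE 0.14). The count that rose was 2 without IP replicate 1 or input replicate 3, 3 without IP replicate 2 or input replicate 2 and 12 without IP replicate 3, and 3 fell without input replicate 2, while 2 rose and 7 fell with upper-quartile scaling. Of 22 immediate early genes 3 rose, 8 fell and 11 did not pass (10 fell adjusted over the list alone, adjusted p 0.539), with Arc, a synaptic plasticity gene, at -1.19 (SE 0.18) and Jund up by 0.96 (SE 0.14), and 5 fell without input replicate 3.

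The camera test with its preset correlation called 14 of the 30 lists, 4 upward and 10 downward, and with an estimated correlation 0, where 3 had an unadjusted p under 0.05. Another division of the same 6 libraries gave 24 called lists, so the preset p-values are best read with the member counts. Signs of median and mean or test differed for the glutamatergic, potassium channel, neuropeptide, cerebellar, LIM homeodomain and both receptor lists. With upper-quartile scaling the sign of the median flipped for the glutamatergic list (0.02 to -0.13) and for GABA and glycine receptors (0.13 to -0.02), and no other list flipped under any scaling.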

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

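The tests chosen only after the result was seen are the comparison of oxidative phosphorylation and forebrain genes with pan-neuronal genes and the test of granule cell genes in input replicate 2, and the Purkinje cell pattern itself was picked after library values were seen. Alignments that were not unique, which no gene count uses, averaged 44.24% of counted lines in IP, above the level of every input library (31.9% to 33.0%), and were picked out for that reason.

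Nuclear genes of oxidative phosphorylation had a median log2 fold change of 1.43. Random lists of tested protein-coding genes matched on transcript length and abundance had a median of 0.859 (0.724 to 0.971 for the central 95%), lower by 0.572, which argues against short and abundant transcripts as the whole cause, although length and abundance go with part of the rise. The list exceeded the pan-neuronal median by 0.576 (permutation p 0.00021, two-sided). The permutation and the random lists treat genes as independent, while the estimated correlation within the list was 0.705. The permutation p and the central 95% therefore do not measure the spread between samples. Without any 1 library, the list median was 1.32 or higher and the pan-neuronal median 0.96 or lower. In these libraries that argues against removal of non-neuronal RNA alone. The pan-neuronal genes were not matched to this list on transcript length or abundance. Removal of non-neuronal RNA acting together with a length or abundance effect was not tested and stays open. A higher share of these transcripts on the ribosomes of tagged neurons may remain as a hypothesis, and RNA left out of polysomes in input was not tested.

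Genes of neighbouring regions differed between libraries. The forebrain list had a median of -2.15 without input replicate 3, so that library alone is not the cause. The rise of 20 of 25 pan-neuronal genes argues against a general loss of neuronal RNA. The forebrain median differed from the pan-neuronal median by -3.517 (two-sided permutation p 1e-05, the smallest the permutations can give). Both medians had been seen before, and the permutation treats genes as independent, so this p adds no further evidence. For the Purkinje cell genes of IP replicate 2, 5 further Purkinje genes written down before their values were read had a median ratio of 1.58 to the higher of the other IP libraries, which lies between the bounds set for and against cerebellar tissue and leaves it open. Homer3 had a ratio of 31.7 and Grid2ip 4.98, against 1.58 for Rgs8 and 1.25 for Slc1a6. The granule cell genes had a median ratio of 13.09 in input replicate 2, but it lies between Gabra6 (39.1) and Cbln3 (24.3) on one side and Fat2 (1.91) and Cdh15 (1.13) on the other, and as Fat2 and Cbln3 had been seen before, cerebellar RNA in that library stays open.

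From the largest rises 7 transcription factor genes that background knowledge ties to the mammillary region, among them Foxb1, Lhx1, Lhx5, Nkx2-1, Sim1 and Uncx, were picked out after their values were seen, with no fixed list behind the set. Of 10 further markers of that and adjoining regions written down before their values were read, 8 were tested and 2 rose, Sim2 (log2 fold change 3.40, SE 0.79) and Foxa1 (2.57, SE 0.37), while Lmx1a fell by 2.73 (SE 0.46). The median was 0.68 and the camera test pointed upward without a call (p 0.346). The bound set beforehand against a mammillary origin of the tagged neurons, fewer than 3 rising or no upward call, was thus met, and the prediction failed. A mammillary origin was left open only after these values were known, because 6 of the 8 markers average under 1.5 log2 CPM. The lowest IP library exceeded the highest input library by a median ratio of 7.59 over the 7 genes (2.72 to 11.94), above the bound of 2 set beforehand. For these 7 genes that argues against 1 IP library alone as the source of the rise. The rule for the largest rises asks for 1 direction in all 3 pairs but does not set the size of the ratio. Genes high in 1 IP library alone would tend to fail that rule, so the ratio says nothing about genes outside the set. Lhx5, named before the data, had a ratio of 11.94.

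The 6 libraries make 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many genes higher (4467), lower (4794), over 2-fold higher (387) or over 2-fold lower (2214), and the highest of the other splits was 0 for each by edgeR's quasi-likelihood test, with at most 286 genes at an unadjusted p under 0.05 against 10249 in the real split. As many called gene lists as the 14 of the real split came from 6 of the 10 splits, with 24 as the highest of the others. Such counts point to a structure of the samples that the preset correlation does not cover. Of the splits, 4 part all 3 same-numbered pairs, the real one included, and the 24 lists came from another of these.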

How the results depend on the processing

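The alternatives chosen only after the data were seen are protein-coding genes only, the set without 4 abundant RNAs, and the set without IP replicate 2 and input replicate 3. Of the 9261 genes called, 0 were called in the opposite direction in any alternative run. Lhx5 stayed higher in all 22 settings, at log2 fold changes of 3.58 to 4.13 and adjusted p of 0.00268 or less. Genes higher in IP ranged from 2847 to 4572 when libraries or pairs were left out, genes lower from 3561 to 4783, genes over 2-fold higher from 204 to 347 and over 2-fold lower from 1223 to 2134, and fewer samples enter these fits. Called lists ranged from 14 to 15 when libraries or pairs were left out, and were 16 without IP replicate 2 and input replicate 3, where the dopaminergic and serotonergic lists were called (0.0298 and 0.0382, and 0.767 for both with an estimated correlation), 13 with upper-quartile scaling or library totals and 12 with protein-coding genes only. Genes over 2-fold higher were 245 with upper-quartile scaling and 248 with protein-coding genes only, where fewer genes were tested. With libraries left out, the camera adjusted p ranged from 5.72e-05 to 0.122 for the ependymal and choroid list, from 0.00245 to 0.805 for the dopaminergic list and from 0.0262 to 0.958 for the serotonergic list. The ependymal and choroid list was also lost with upper-quartile scaling (0.0584) and library totals (0.0545), and the ribosomal protein list with protein-coding genes only (0.0708). The cause was not tested. With an estimated correlation 0 lists were called. The adjusted p was 0.115 for oligodendrocyte precursors, 0.116 for oligodendrocytes, 0.215 for nuclear noncoding RNAs, 0.365 for the pan-neuronal, astrocyte, microglial and oxidative phosphorylation lists, 0.392 for the mural, blood and forebrain lists, 0.573 for endothelial genes, 0.618 for histones and 0.801 for ribosomal proteins and for ependymal and choroid genes. With the replicate block, which pairs libraries of a shared lane, 4811 genes were higher and 4879 lower, 405 and 2032 past 2-fold. The block ended the calls of Isl1 (adjusted p 0.208), Pdyn (0.112) and Ppp1r1b (0.193) and of no other named gene or list. DESeq2 and limma-voom each kept 99% of the calls, upper-quartile scaling kept 88.8%, and 68%, 70.2% and 89.3% were kept without pairs 1, 2 and 3 and 79% without IP replicate 2 and input replicate 3. Of 132 named genes, 125 kept their call with upper-quartile scaling, 114 without IP replicate 2 and 111 without pair 2.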

Other observations

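The gene families in this part were all chosen only after the data were seen. None was compared with genes matched on transcript length or abundance, so a share of their changes that goes with these was not tested. Random lists matched to the oxidative phosphorylation genes had a median of 0.859. Log2 fold changes fell with transcript length over 14600 other protein-coding genes (Spearman correlation -0.248). Of 76 mitochondrial ribosomal protein genes, which build the ribosomes inside mitochondria, 70 rose, 0 fell and 6 did not pass, with a median log2 fold change of 0.96 (camera adjusted p = 5.67e-20 over 15 families, and adjusted p = 0.35 with an estimated correlation). Of 42 genes picked by proteasome names, not all of them subunits, 32 rose, 1 fell and 9 did not pass. Psma7 stood at 0.89 (SE 0.10) and Psmb4 at 0.66 (SE 0.10), and the median was 0.62 (adjusted p = 9.7e-07, and adjusted p = 0.35 with an estimated correlation). Of 20 vacuolar ATPase genes 12 rose, 1 fell and 7 did not pass (adjusted p = 0.00376, and adjusted p = 0.35 with an estimated correlation). Of 12 tubulin genes 9 rose and 3 did not pass, with the neuronal Tubb3 at 1.07 (SE 0.14) (adjusted p = 0.0091, and adjusted p = 0.52 with an estimated correlation). Of 27 synaptic vesicle and SNARE genes 13 rose, 3 fell and 11 did not pass, with Vamp1 at 1.62 (SE 0.36) and Rab3a at 1.24 (SE 0.13) (adjusted p = 0.0238, and adjusted p = 0.492 with an estimated correlation). Of 53 genes picked by names of translation initiation factors, kinase genes among them, 23 rose, 5 fell and 25 did not pass. Their median was 0.18 (adjusted p = 0.0294, and adjusted p = 0.52 with an estimated correlation). It was 0.02 with upper-quartile scaling, where 17 rose and 8 fell. No median of the other families named in this paragraph changed sign under any scaling.

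Of 36 collagen genes 22 fell, 0 rose and 14 did not pass, with Col1a2 at -3.06 (SE 0.44) and Col6a1 at -4.65 (SE 0.65) and a median of -2.42 (camera adjusted p = 0.000177, and adjusted p = 0.224 with an estimated correlation). Serotonin receptors differed from one another, with 5 of 13 higher, 3 lower and 5 not passed (adjusted p 0.519). Htr1d rose by 2.82 (SE 0.41) and Htr2a by 1.40 (SE 0.16), while Htr5b fell by 3.31 (SE 0.63). Among 16 acetylcholine receptor genes 3 rose, 4 fell and 9 did not pass (adjusted p 0.872), against 1 and 5 with upper-quartile scaling, with the muscarinic receptor gene Chrm5 up by 2.70 (SE 0.38) and the nicotinic subunit gene Chrnb3 down at -2.37 (SE 0.53). Of 352 zinc finger genes 62 rose, 68 fell and 222 did not pass (adjusted p 0.872), and with upper-quartile scaling 34 rose and 92 fell and their median went from 0.01 to -0.15. Of 64 protocadherin genes 5 rose, 5 fell and 54 did not pass (adjusted p 0.794), and with that scaling 3 rose and 7 fell and their median went from 0.03 to -0.12. The families of chaperonin subunits (0.347), dopamine and adrenergic receptors (0.872), major histocompatibility and complement genes (0.462) and C1q-like genes (0.0634) were not called at these adjusted p-values.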
